A study of Drosophila melanogaster with 4 samples.

How the data were processed

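Chromatin came from wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 h, crosslinked with 1.8% formaldehyde, per the labels' protocols. The 4 libraries were 2 H3K27ac ChIP libraries, replicates 1 and 2, and 2 input libraries, each named in the labels as the input of a single ChIP list. Grouping followed the sample titles. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The peak caller, its threshold, its filters and the way the replicates were joined into the combined list are not given in the sources used here.

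The authors deposited a list of enriched regions for each ChIP replicate, called per library, and a list for the replicate set. Per the file headers, positions are on FlyBase release 5. Each region carries a score deposited by the authors, which is the region's own value within its list. The scale of this score is not stated. The only region marked as depleted has a value below 0. Pairs of distinct values that lie exactly 1 apart (tolerance 1e-09) numbered 20 in the combined list, 36 in replicate 1 and 43 in replicate 2, while no nearby step tried gave more than 1 such pair. A doubling on a natural log scale, a step of 0.693, gave 1, 0 and 0 such pairs, and on a log10 scale, a step of 0.301, gave 0 in each list. The score is therefore read as having the spacing of a log2 ratio, a reading taken from the values alone. It was used to describe, rank and pair regions, and no change in acetylation was read from differences between lists. All 7474 enriched regions of the combined list have even starts and ends.

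Region width was taken as end minus start, with which the narrowest widths are 1300 bp in both replicates and 1000 bp in the combined list. A single region of replicate 1 starts at 0, so printed positions may be off by 1 base. Arm and scaffold lengths came from the file headers. The depletion region was left out of all counts. The lists hold no read counts, so the depth per library is unknown, and no interval or detection limit that needs it is given. No list of the input libraries was analysed here, so the background in input cannot be given beside the values.

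Replicate lists were compared by overlap of at least 1 bp against 1000 random placements of the other list within the same arm, keeping numbers and widths, as a one-sided permutation test. Values of clusters that overlap only each other were compared by Spearman and Pearson correlation with two-sided permutation tests of 100000 resamples. Combined clusters were sorted by whether they overlap both, a single or neither replicate list, without a test. The covered share of each arm is the mean and SD of 2 replicates. A difference between arms was called where both replicates had the same direction and the mean difference exceeded its SD, since 2 libraries allow no exact test under 0.05. For normally distributed values this rule calls 39.2% of contrasts that hold no difference. Bins of 1 Mb, 2 Mb arm ends, the class of broad clusters of at least 20000 bp and the limit of 1 for high values were chosen after the data were seen. So were the 5 arm contrasts.

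The tests of overlap, paired values and covered shares, the rule for named regions and the main alternatives were fixed before the data were examined. By that rule, the regions named are the 10 combined clusters with the highest value, the 10 widest, and for each arm the widest stretch without a cluster in any list. Tests of gene features and gene lists were also planned. They were not run, since the gene table at hand is on release 6 of the genome, no annotation of release 5 was used here and positions were not converted between releases. No gene is therefore named at any region.

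The alternatives were clusters with values above the median of their list, merging of clusters less than 500 bp apart, a minimum width of 500 bp, a reciprocal overlap of 50%, the share of bases, placement within blocks of 1 Mb, clusters per Mb, and each replicate alone. Leaving out arm ends of 2 Mb, and keeping only combined clusters at least as wide as the narrowest replicate cluster, were added after the data were seen. The overlap test was checked on simulated data for the overlap of replicate 1 with replicate 2, on the 6012 clusters of the long arms. Among 50 simulated pairs without shared placement, drawn by the placement rule of the test itself and judged with fewer placements, 1 gave a p below 0.05. This checks the computation, not whether random placement suits real clusters. With 60.8% of clusters planted as shared, 66.6% were found to overlap, which includes overlap by chance. To match clusters of the heterochromatic scaffolds, chromosome 4 and U, each was replaced at random by 1 of the 50 long-arm clusters of the same list nearest in rank of value and width, in 10000 draws. Intervals for shares of clusters are exact Clopper-Pearson intervals at 95% confidence and cover counting error only. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures used matplotlib 3.10.9.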

Results

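Acetylation of histone H3 at lysine 27 (H3K27ac), a chromatin mark found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 h. At this age organs have formed and the nervous system, muscle and cuticle are maturing. The series holds 4 libraries, of which 2 were immunoprecipitated with an H3K27ac antibody and 2 were input chromatin, each input being the reference of a single ChIP replicate. For each ChIP replicate the authors deposited a list of enriched regions, called clusters here, with a value per cluster. A further list was made by the authors from the replicate set and is called the combined list. The lists give no read counts, so the sequencing depth behind them is unknown. Positions are given on FlyBase release 5 of the genome, as deposited. Nothing in the labels says that the replicates came from separate embryo collections, so the spread and the p-values given for them may be technical.

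H3K27ac clusters covered a similar part of the genome in each replicate. Replicate 1 had 6223 clusters covering 27.7 Mb, or 19.8% of the assembled arms, the heterochromatic scaffolds and the unplaced sequence U. Replicate 2 had 6317 clusters covering 28.5 Mb, or 20.4%. The mean was 6270 ± 66.5 clusters and 28.1 ± 0.595 Mb (SD, n = 2). Most clusters spanned a few kilobases. The median width was 2889 bp in replicate 1 and 2964 bp in replicate 2, the lower quartiles were 2000 and 2018 bp, and the upper quartiles were 5077.5 and 5078 bp. A small class of broad clusters of at least 20000 bp numbered 102 in replicate 1 and 112 in replicate 2. These broad clusters held 10.6 ± 0.427% (SD, n = 2) of all covered bases, and the widest reached 65316 bp in replicate 1 and 63589 bp in replicate 2. The deposited value, whose spacing is that of a log2 ratio, had a median of 0.69 in replicate 1 and 0.75 in replicate 2. Wider clusters had higher values, with a Spearman rho across clusters of 0.832 in replicate 1 and 0.833 in replicate 2. Clusters are not independent replicates, and the width limit of 20000 bp for the broad class was chosen after the widths were seen.

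Most regions acetylated in either library were acetylated in the other. Of the replicate 1 clusters, 5531 (88.9%) overlapped a replicate 2 cluster by at least 1 bp. Of the replicate 2 clusters, 5439 (86.1%) overlapped a replicate 1 cluster. All 102 broad clusters of replicate 1 and all 112 of replicate 2 were among those shared. Wide clusters overlap the other list by chance more often than narrow ones, and no chance rate by width was computed. The 692 clusters seen in replicate 1 alone were narrow, with a median width of 1654 bp against 3193 bp for the shared clusters, and had a median value of 0.48 against 0.74. The 878 clusters seen in replicate 2 alone had a median width of 1687.5 bp against 3343 bp and a median value of 0.50 against 0.82. Random placement of the other list within the same chromosome arm, with cluster numbers and widths kept, gave overlaps of 41.0 ± 0.591% for replicate 1 and 40.3 ± 0.597% for replicate 2 (SD over 1000 placements). The observed shares were 2.17 and 2.14 times these means, and no placement exceeded 42.8% and 42.3%. The one-sided permutation p was 0.001 for both, the smallest that 1000 placements can give. Bases covered in both replicates came to 24.8 Mb of the 31.4 Mb covered in either, a Jaccard index of 78.9% against 13.1 ± 0.258% for random placement (one-sided permutation p = 0.001, the smallest possible). These tests compare the lists of 2 libraries, and do not take in variation among embryo collections.

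Among clusters paired between the lists, those with the highest values in replicate 1 tended to have the highest values in replicate 2. Clusters without a partner were left out, such as a replicate 2 cluster of value 3.25 on 3L, where the highest value of that list was 3.34. Among 4403 pairs of clusters that overlapped only each other, Spearman's rho was 0.884 and Pearson's r was 0.927. The two-sided permutation p was 1e-05 for each, the smallest that 100000 resamples can give, and the correlation runs across regions, which are not independent. Cluster boundaries lay a median of 160 bp apart at the start and 166 bp apart at the end. The rank correlation was higher among the wider pairs (rho 0.90, 2199 pairs) than among the narrower pairs (rho 0.66, 2204 pairs), and the difference between these correlations was not tested. Width and value rise together, so these sets may differ in their range of values, which alone can change rho. Replicate 2 had the higher value in 2954 pairs (67.1%), with a median difference, replicate 2 minus replicate 1, of 0.07 and an SD across pairs of 0.15. As each value belongs to its own list, this difference is not a measure of acetylation.

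**Figure D1:**
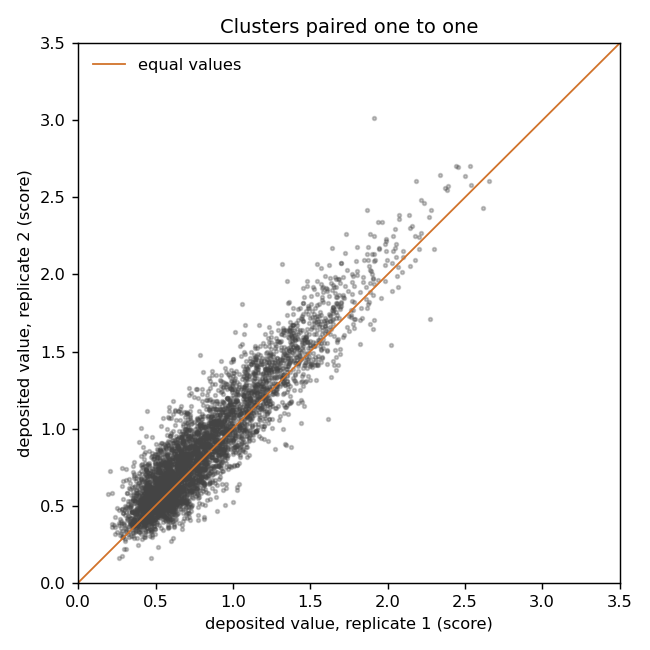
Deposited value of each pair of clusters in replicate 1 (x axis, score) and replicate 2 (y axis, score), with a line of equal values. Each of the 4403 points is a pair of clusters that overlap only each other, and 67.1% of the points lie above the line.

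The combined list held 7474 enriched clusters covering 34.5 Mb. In all, 4856 of them (65.0%) overlapped clusters of both replicates. These were the wide and strongly enriched regions, with a median width of 4240 bp, a median value of 0.73 and 30.0 Mb of the covered length. A further 1379 (18.5%) overlapped a cluster of a single replicate, 602 of them in replicate 1 and 777 in replicate 2, with a median width of 1862 bp and a median value of 0.34. The remaining 1239 (16.6%) overlapped no cluster of either replicate and had a median width of 1302 bp and a median value of 0.34. Of these, 613 (49.5%) were narrower than 1300 bp, the narrowest width in either replicate list, whereas the combined list went down to 1000 bp. Nearly every replicate cluster was in the combined list, with 6197 (99.6%) of replicate 1 and 6268 (99.2%) of replicate 2. Because the combined list was made from the same libraries, it is no independent evidence for the replicate clusters. A single region of depletion was listed, on 2R from 19980956 to 19982572, with a value of -0.02, and no replicate cluster overlapped it.

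The widest H3K27ac domain of the combined list lay on 3L from 759896 to 829836 and spanned 69.9 kb, with a value of 1.16. It formed a single cluster of 63.6 kb in replicate 2 and 3 clusters in replicate 1. A second domain on 3L, from 11356662 to 11424282, spanned 67.6 kb (value 1.57), and another on 2R, from 6401178 to 6463946, spanned 62.8 kb (value 1.83). By the summed width of the replicate clusters the second domain on 3L was wider than the first, at 67.2 ± 0.495 against 64.25 ± 0.933 kb (SD, n = 2). The domain on 3R from 12030006 to 12087674 was both wide (57.7 kb) and high (value 2.57). It was a single cluster in each replicate, of 57.6 kb with value 2.44 in replicate 1 and 57.5 kb with value 2.71 in replicate 2. On 3R from 898482 to 953102 a domain of 54.6 kb had a value of 1.47, and replicate widths of 54.5 and 54.3 kb. The domain on 3L from 19137124 to 19191054 (53.9 kb, value 1.15) was divided into 4 clusters in replicate 1 and 5 in replicate 2. The others of the 10 widest were on 2R from 12687146 to 12738736 (51.6 kb, value 1.93) and on 3L from 605346 to 655294 (49.9 kb, value 2.34). On X they lay from 6859702 to 6909366 (49.7 kb, value 1.83) and from 12608552 to 12656544 (48.0 kb, value 2.21). All 10 overlapped clusters of both replicates, and 5 were a single cluster in each. On 3L lay 4 of them, with 2 each on 2R, 3R and X.

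Of the 10 combined clusters with the highest values, 4 were found in both replicates. The highest of these lay on 2R from 5426400 to 5457114 and spanned 30.7 kb with a value of 3.10, with 3.06 in replicate 1 and 3.34 in replicate 2 (mean 3.20 ± 0.20, SD, n = 2). Next were 2R from 1145288 to 1149210 (3.92 kb, value 2.63, replicates 2.66 and 2.61) and 2R from 19757022 to 19763664 (6.64 kb, value 2.60, replicates 2.53 and 2.71). The last was the 57.7 kb domain of 3R named above. The other 6 were 1000 to 1146 bp wide and overlapped no cluster of either replicate. A pair of them, on 3R at 3534182 to 3535328 and at 17134082 to 17135084, shared the value 3.33, the highest of the list. Those on 2R at 16630670 to 16631670 and on X at 14177426 to 14178426 shared the value 3.04. Those on 2L at 22808756 to 22809756 and on X at 5375220 to 5376220 shared the value 2.87. Among clusters found in both replicates, the 10 highest values lay on 2R (4 clusters), X (3 clusters), 2L, 3L and 3R (1 cluster each), a list drawn up after the values were seen. It took in 6 more, the highest of them on X from 9044640 to 9051592 (6.95 kb, replicate mean 2.57 ± 0.10), on 2R from 16882780 to 16890016 (7.24 kb, 2.56 ± 0.03) and on X from 6740772 to 6774228 (33.5 kb, 2.58 ± 0.17; SD, n = 2).

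The covered share differed between chromosome arms. X and 2R were covered most among the 5 long arms, at 25.5 ± 0.177% and 25.5 ± 0.652%, followed by 3L at 23.1 ± 0.584%, 3R at 21.8 ± 0.924% and 2L at 19.9 ± 0.519% (SD, n = 2). The X chromosome exceeded the pooled 4 long autosomal arms, at 22.5 ± 0.681%, by 3.04 ± 0.505 percentage points, with 3.40 in replicate 1 and 2.69 in replicate 2. No difference in share was called between X and 2R, with X minus 2R at 0.394 points in replicate 1 and -0.278 in replicate 2. By clusters per Mb X lay below 2R (-2.79 ± 1.00), and by the share covered by clusters above the median value of their list it lay above (1.60 ± 0.507 points), both called. X clusters also had the highest median value of the long arms in both replicates, 0.75 and 0.82, against 0.67 and 0.72 for clusters of the long autosomal arms. Between the arms of chromosome 2, 2R exceeded 2L by 5.57 ± 0.133 points, with 55.7 ± 0.401 clusters per Mb on 2R and 47.3 ± 1.35 on 2L. With 2 replicates no exact test can reach 0.05, so an arm difference was called where both replicates had the same direction and the mean exceeded its SD. This rule is lenient, as it calls 39.2% of contrasts without any difference if replicate values are normally distributed, and the 5 arm contrasts were picked after the shares were seen.

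The heterochromatic scaffolds, which hold repeat-rich sequence next to the centromeres and from Y, were sparsely marked. Together they were covered at 2.55 ± 0.516%, against 23.1 ± 0.586% for the long arms, a difference of -20.5 ± 1.10 percentage points (SD, n = 2). Coverage was 4.28 ± 0.468% on 2LHet, 2.14 ± 0.424% on 2RHet, 2.97 ± 0.547% on 3LHet and 1.74 ± 0.668% on 3RHet. XHet stood apart at 14.5 ± 0.264%, from 9 clusters in each replicate. YHet held 2 clusters in replicate 1 and 0 in replicate 2, and U was covered at 0.768 ± 0.125%. Chromosome 4, small and largely heterochromatic, had 59.2 ± 1.05 clusters per Mb against 51.0 ± 0.754 on the long arms, 8.14 ± 1.80 more. Its covered share of 26.4% in replicate 1 lay above that of the long arms by 3.75 points and its 21.9% in replicate 2 lay below (-1.56 points), so no difference in share was called. None of its clusters was broad. The depth being unknown, a scaffold with few clusters cannot be told from a scaffold where reads could seldom be placed.

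**Figure D2:**
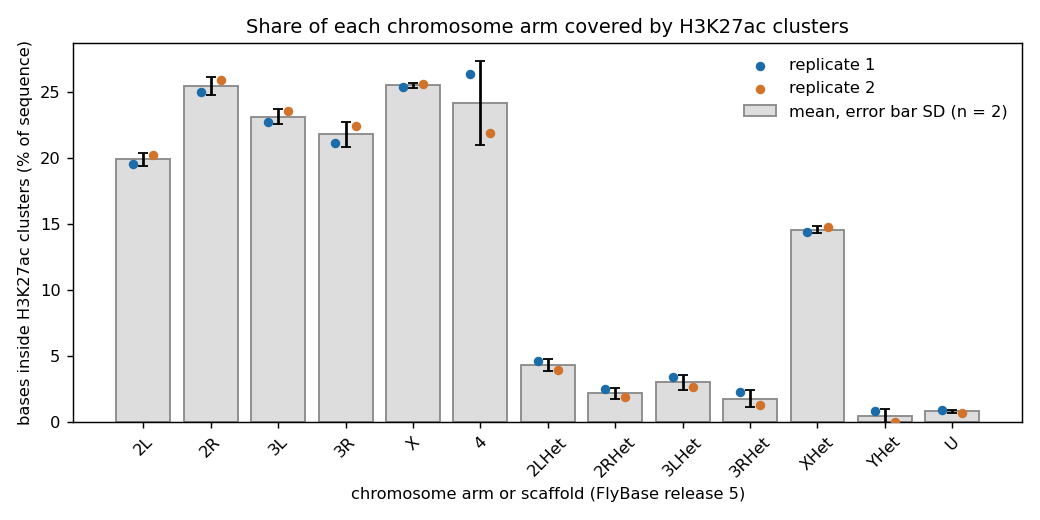
Percent of the bases of each chromosome arm or scaffold (x axis) that lie inside H3K27ac clusters (y axis), as the mean (bar) with SD (error bar, n = 2) and the value of each replicate (points). X and 2R are covered at 25.5%, and the heterochromatic scaffolds other than XHet at under 5%. In percentage points the replicates differ most on chromosome 4. By ratio, replicate 1 over replicate 2, they differ more on 3RHet (1.75) than on chromosome 4 (1.20).

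Coverage along the long arms varied in much the same way in both replicates, by a correlation over the bins of all arms together. Across the 117 full bins of 1 Mb on the long arms, the covered share had a median of 23.5%, with quartiles of 18.5% and 27.6%. Between replicates it had a Spearman rho of 0.984 and a Pearson r of 0.984. The two-sided permutation p was 1e-05, the smallest possible, across bins that are not independent. The most covered bin was the first of 3L, from 1 to 1000000, at 49.4 ± 0.347%, and it contains the domains at 759896 and 605346. Next were 3R from 5000001 to 6000000 at 39.9 ± 2.20% and X from 1000001 to 2000000 at 38.5 ± 0.874%. The least covered were 2L from 15000001 to 16000000 at 5.09 ± 0.457%, 3L from 23000001 to 24000000 at 7.84 ± 1.92% and 3R from 3000001 to 4000000 at 9.37 ± 0.986% (SD, n = 2).

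The 2 Mb at the centromere end of the assembled arm were covered less than its middle in 4 of the 5 long arms, in both replicates. Whether reads could seldom be placed at these ends was not tested. On X the values were 9.15 ± 0.0952% and 26.4 ± 0.199%, on 3L 9.35 ± 1.98% and 23.0 ± 0.901%, on 2R 14.1 ± 1.85% and 26.7 ± 0.886%, and on 2L 16.3 ± 0.222% and 19.4 ± 0.564% (SD, n = 2). On 3R the centromere end was covered more, at 30.9 ± 0.865% against 21.1 ± 0.844%. The centromere ends of 2L (16.5 against 16.1%), 2R (15.4 against 12.8%) and 3L (10.8 against 7.95%) were covered more in replicate 1 than in replicate 2. Those of 3R and X, and the middle of every long arm, were covered more in replicate 2. The 2 Mb at the telomere end of the assembled arm were covered more than the middle on 3L (38.7 ± 0.106%), X (34.1 ± 0.0503%) and 2L (28.5 ± 0.829%). On 2R the telomere end was at 26.2 ± 1.14%, below the middle in both replicates, and on 3R, at 20.4 ± 1.94%, the replicates differed in direction. The widest stretches without a cluster in any list were 339.8 kb on X from 21503727 to 21843488 and 330.9 kb on 2L from 17782457 to 18113398. They were 258.2 kb on 3R from 23891215 to 24149390, 250.7 kb on 2R from 16216569 to 16467236 and 238.1 kb on 3L from 23741537 to 23979635. On chromosome 4 the widest was 61.9 kb, from 810522 to 872380. The bins and the 2 Mb ends were chosen after the data were seen.

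**Figure D3:**
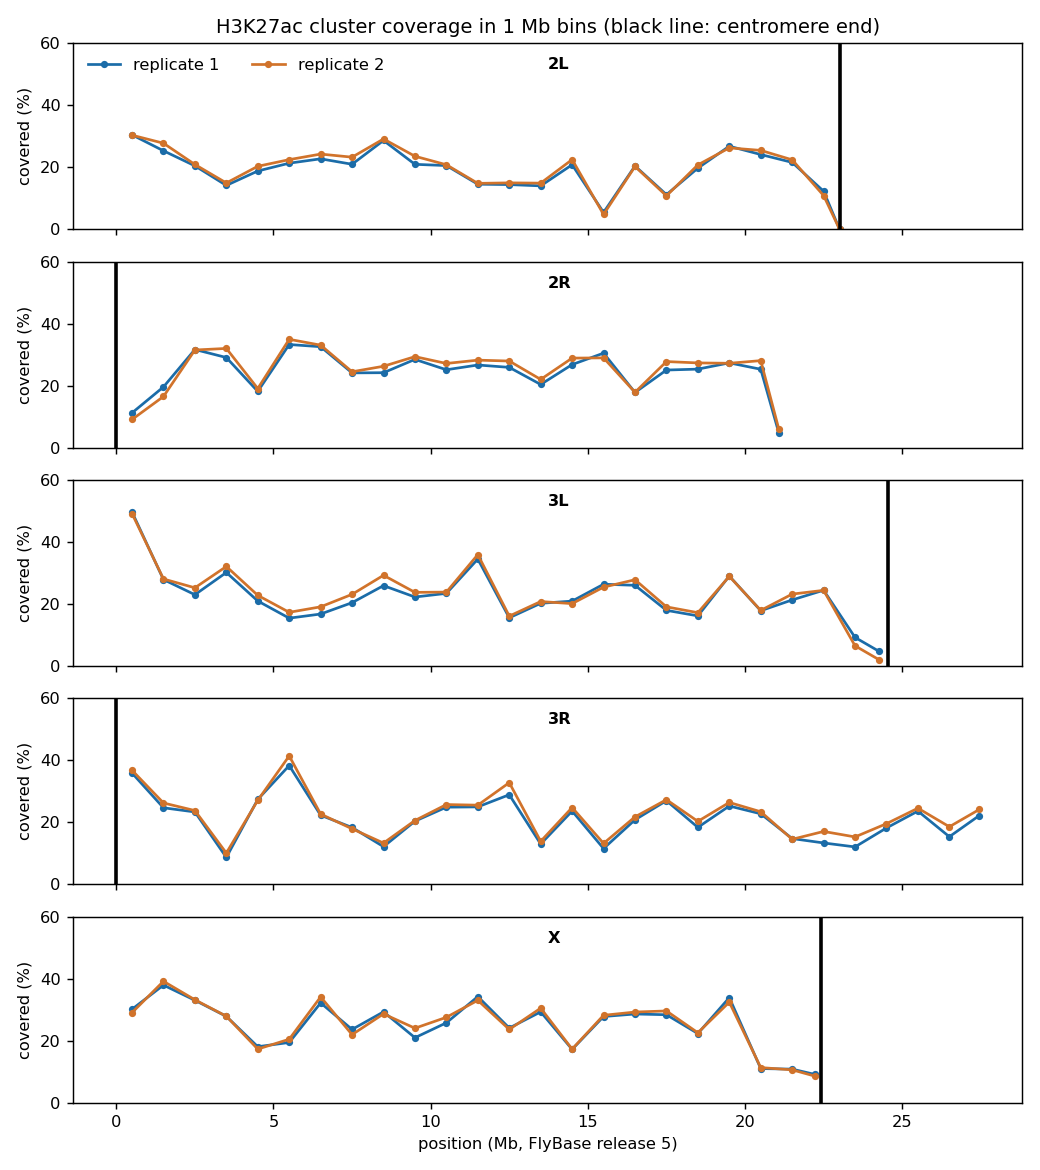
Percent of bases inside H3K27ac clusters (y axis) in bins of 1 Mb along the 5 long arms (x axis, position in Mb on FlyBase release 5) in replicate 1 and replicate 2, with a black line at the centromere end of each arm. Both replicates follow much the same course. Full bins run from 49.4% in the first of 3L down to 5.09% in that of 2L from 15000001 to 16000000. Shorter bins at the arm ends are drawn too, and the last of 2L is at 0.0%.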

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

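The alternatives that left out arm ends or narrow combined clusters, and the arm contrasts themselves, were chosen after the data were seen. Sharing between replicates stayed above every random placement with a reciprocal overlap of 50% (77.7% of replicate 1, 76.5% of replicate 2), among clusters above the median value, after merging, by bases and within 1 Mb blocks. Placement within blocks let placed clusters overlap one another, unlike placement within the arm. Its chance means, 36.8% for replicate 1 and 36.3% for replicate 2, were below the 41.0% and 40.3% of placement within the arm, so it is no stricter test. The paired values gave rho 0.90 with reciprocal overlap of 50%. The contrasts of X with the long autosomal arms, of 2R with 2L and of the heterochromatic scaffolds with the long arms kept their direction under every alternative run, and their call under those that use both replicates. X with the autosomal arms ranged from 2.69 points in replicate 2 alone to 4.51 above the median value. Of the alternative values, 47 kept their side of the call or test, moved by less than the spread or, for the number of clusters, stayed within 1.5 times the reported count, and the others are given next.

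Keeping clusters above the median value left, by its construction, 3135.5 clusters per replicate covering 20.9 Mb, with a median width of 4854 bp. Merging lowered the number of clusters per replicate from 6270 to 5625.5, beyond the SD of 66.5, and raised the median width to 3169 bp. The share of combined clusters found in both replicates was 61.5% when 50% of the cluster had to be covered, 68.0% above the median value and 71.8% among those at least as wide as the narrowest replicate cluster (65.0% as reported, 95% interval 63.9 to 66.1). Chromosome 4 exceeded the long arms by 8.14 clusters per Mb, while its share went from -1.56 points in replicate 2 alone to 3.75 in replicate 1 alone. X minus 2R was -2.79 clusters per Mb, 1.60 points among clusters above the median value and -0.337 points without 2 Mb at both ends. The differences per Mb and the 1.60 points were called, unlike those reported for the whole arms. The cause of the changes in these contrasts was not tested. A minimum width of 500 bp removed no cluster and so tests nothing. The alternatives planned for gene features and gene lists were not run. No paired analysis was possible because the inputs that share replicate numbers with the ChIP libraries have no list used here. Unknown depth limits what the absence of a cluster means.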

Other observations

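In this part, only the tests of neighbouring widths were chosen before their results were seen, and the other tests came after. The median value of the chromosome 4 clusters was 0.89 in replicate 1 and 0.83 in replicate 2, above that of the long arms by 0.21 in replicate 1 and 0.09 in replicate 2, so the size of the difference depends on the library. In replicate 2 it was about level with X, at 0.82. Its 81 and 79 clusters were wider than those of the long arms by 685.5 bp in replicate 1 and 156 bp in replicate 2, by median width. In replicate 2 they were narrower than those of X, at 3141 against 3219 bp. Median values of the few clusters on the heterochromatic scaffolds were 1.04 ± 0.25 on 2LHet, 1.00 ± 0.04 on 3LHet, 0.83 ± 0.03 on 2RHet, 0.81 ± 0.12 on XHet and 0.80 ± 0.02 on 3RHet (SD, n = 2). The long autosomal arms had 0.70 ± 0.04 and X had 0.79 ± 0.04. Compared within each library, 2RHet lay slightly above X, at 0.80 against 0.75 in replicate 1 and 0.85 against 0.82 in replicate 2. The median of 3RHet was 0.79 in replicate 1 and, in replicate 2, level with X at 0.82. On XHet the median of replicate 1, 0.73, lay below the 0.75 of X. Of the clusters in a single replicate, the highest value in replicate 2 was 3.25, on 3L from 23514112 to 23516130, and in replicate 1 it was 1.86, on 3LHet from 2382149 to 2383674.

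Of the 10 highest values of the combined list, 6 lay in narrow clusters that neither replicate had, while most clusters with a value of at least 1 were in both replicates (1349, against 27 in neither). The 6 came in pairs of equal values, which prompted a test on the clusters outside the 10 highest. There, the value of 4 of 21 in neither replicate (19.0%) recurred exactly at another cluster, against 8 of 1345 (0.595%) in both (Fisher's exact test, two-sided, p = 1.89e-05). Recurring values were common in the whole list, at 702 of 7474 (9.39%), and more so among clusters of value under 1 narrower than any replicate cluster (232 of 687, 33.8%). A ratio of few reads may therefore lie behind the highest values, but it cannot be separated from the lower width limit of the combined list, since 24 of the 27 (88.9%, 95% Clopper-Pearson interval 70.8 to 97.7) were narrower than any replicate cluster, and no biological explanation was tested.

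Replicate 1 covered more of the heterochromatic sequence and replicate 2 more of the long arms. Of the 7 heterochromatic, chromosome 4 and U sequences with clusters in both, 6 were covered more in replicate 1 (mean log2 ratio, replicate 1 over replicate 2, 0.34), against 0 of the 5 long arms (mean -0.05). On these 7 sequences 50 of 209 replicate 1 clusters had no partner, against 11 of 178 in replicate 2 (Fisher's exact test, two-sided, p = 1.17e-06), a test that describes these 2 libraries alone. Shared clusters count in both lists, so the lists are not the independent samples that the test takes them for. As a set, replicate 1 clusters of these sequences were not low in value. Their medians ran from 0.73 on XHet to 1.21 on 2LHet, against 0.67 for the long autosomal arms. Draws matched in value alone held 7.46% without a partner, below the 10.65% of the long arms, so they could hardly favour low values as the cause. The clusters without a partner were low, with a median of 0.52 (YHet included) against 0.48 on the long arms. Long-arm clusters of replicate 1 drawn to match the clusters of these sequences in value and width held 19.2 ± 3.70 without a partner (SD over 10000 draws) and 35 at most. Narrow widths are therefore argued against as the whole cause of the replicate 1 excess. The matched draws of replicate 2 held 23.2 ± 3.75, above its 11. All draws come from the long arms, where replicate 2 covered more, so they carry that difference between libraries. The depth of each library, its calling threshold and the placing of reads in repeats stay open, untested, as does any biological explanation.

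Wide clusters had wide neighbours only weakly, with a Spearman correlation of the widths of adjacent clusters of 0.0183 in replicate 1 (one-sided permutation p = 0.0549), 0.0352 in replicate 2 (p = 0.00699) and 0.0523 in the combined list (p = 0.001, the smallest possible). The replicate values lay within the range of 1000 random orders and the combined value above it. With clusters less than 5000 bp apart merged, the correlation was not lower, at 0.0433 in replicate 1 (permutation p = 0.027), 0.0439 in replicate 2 (p = 0.018; mean of both 0.0436) and 0.0551 in the combined list (p = 0.004), each within the range of random orders. More than 2 Mb from both arm ends it was 0.0044 in replicate 1 (permutation p = 0.388), 0.0352 in replicate 2 (p = 0.00699; mean of both 0.0198) and 0.0385 in the combined list (p = 0.005), again within that range. Splitting of domains and the arm ends both stay open as sources of so weak a pattern, since the tests asked for values above every random order, which the replicates did not reach as deposited, a condition on the replicates set after the correlations were seen.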
